A study of Mus musculus with 6 samples.

How the data were processed

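The series comprised 6 arrays of mouse heart RNA, 3 from mice labelled as overexpressing hAT1R and 3 from normal C57BL/6 mice. Per the labels' protocols, total RNA was extracted from heart tissue with a column kit and biotinylated cRNA was prepared from 6 ug of it. The series design text states that the animals were matched for age and sex. Groups and replicate numbers were taken from the sample titles. The deposited values were on a log2 scale, from about 1 to 16, with 1 value per probe set and array. GCRMA, a background correction and normalization method for Affymetrix arrays, was the tool named in the submitters' processing notes, and its version and any later step are not given in the sources used here. The values were used as deposited. The other deposited files were the instrument's text records. Their fields (other than expression) gave fluidics station, scan order and a name typed into the chip lot field. In them, 2 stations and 1 day of scanning were found. The typed name was never used to assign a group.

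Of 45101 probe sets, 64 Affymetrix control probe sets were left out. Gene names came from the platform annotation of 2016, in which 34945 of the remaining 45037 probe sets had 1 gene, 932 had several and 9160 had none. Of those with 1 gene, 34741 had a gene ID that matched the RefSeq gene table of assembly GRCm38.p6, and no symbol changed. That table was used for names and for gene order alone, and no coordinates are given because the values carry no genome build. Probe sets with several genes were not named. No 2 arrays shared more than 0.0178% of their values, so none was counted as a duplicate.

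A probe set was kept when its mean over the 6 arrays lay above the median of that mean, log2 3.285, which left 22518 probe sets. A gene was represented by its probe set with the highest mean, which gave 11016 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from this limma fit, and log2 changes are given with its moderated standard error as value ± SE. Gene lists were tested on the genes kept with limma's camera at a preset correlation of 0.01, against camera with an estimated correlation and against fry, whose directional p tests whether a set's genes move one way on balance. Lists with fewer than 5 measured genes were not tested. Small groups of values were compared by 2-sided exact permutation.

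The design, the alternatives, the named genes and 32 gene lists were fixed before the data were examined. The named genes were the angiotensin receptors and the main hypertrophy, calcium pump and collagen genes. They also included up to 10 genes with the largest rise and 10 with the largest fall among those that passed without overlap between groups. Where fewer than 5 passed in a direction, the 5 with the smallest p were named. For each list up to 4 passing members were named, or else the 2 with the largest change. A further 18 genes were singled out after their values were seen. The 32 lists covered hypertrophy and fetal genes, adult sarcomere and calcium handling, matrix and fibrosis, fatty acid oxidation, oxidative phosphorylation, the citric acid cycle, glycolysis, ion channels, angiotensin signalling, immediate early genes, cytokines, interferon response, oxidative stress, unfolded protein and heat shock response, cell cycle, cell death and the circadian clock. The others held markers of cardiomyocytes, fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, neutrophils, erythroid cells, adipocytes, atrial myocytes, skeletal muscle, Schwann cells and neurons, epicardium and lung, and sex-linked transcripts. Of 777 genes in the lists, 63 were not analysed here.

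The fit was tested on simulated data drawn for the 22518 probe sets from their means and moderated spreads, with 200 changed in each of 20 runs. It recovered 16.6% of the changes of 0.5, 81.7% of those of 1 and 98% of those of 2 on the log2 scale, and 6.11% of its calls were false. With no change it made 0.05 calls a run on average. In 20 runs with 27 lists of 30 independent probe sets, the list shifted by 0.3 was called in 20, and 0 of 520 unshifted lists were. These lists had no correlation between members. Alternatives covered the brightness filter, quantile normalization, median centring, trended and robust variance, array weights, replicate number or fluidics station as a block, the mean of a gene's probe sets, the set test, and each array left out in turn. Arrays of station 2 alone, and the Xist level as a term, were added after seeing the data. A pseudocount was not needed because the values were on the log2 scale.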

Results

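RNA abundance was measured in mouse heart tissue with Affymetrix whole-genome expression arrays. The series held 6 arrays in 2 groups of 3. Mice of the first group overexpressed hAT1R, the human type 1 receptor of the vasoconstrictor hormone angiotensin II, and those of the second were normal C57BL/6 mice. The comparison asked which cardiac transcripts differ in hearts of the transgenic line. Each array gave values for 45101 probe sets, with a median log2 value between 3.25 and 3.31. Pearson correlations across probe sets, which are not independent replicates, ran from 0.9961 to 0.9967 within the transgenic group. They ran from 0.9952 to 0.9966 within the non-transgenic group and from 0.9933 to 0.9961 between the groups. The labels do not say that each array was a separate animal, so the p-values measure the spread between these samples, and the number of arrays limits the precision. Each group held arrays of both sexes by the sex-linked transcripts given below, so its arrays were not all repeats of a single sample. Part of the spread may still be technical.

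The instrument's own records did not carry the same group names as the sample labels. On all 6 arrays the name typed into the record's chip lot field held the other group's word. It was "control" on the 3 arrays labelled transgenic and "transgene" on the 3 labelled non-transgenic. The groups below follow the sample labels, and "labelled transgenic" is written for that reason. Taking the typed names instead would turn the sign of every difference. No probe set used here was annotated to the human transgene, so the receptor itself could not check the labels. The mouse receptor gene Agtr1a was at log2 9.93 ± 0.04 (SD, n = 3) in the labelled transgenic group and 9.99 ± 0.55 in the other. Its change was -0.05 ± 0.26 (SE), adjusted p = 0.946, with a 95% interval from -0.69 to 0.58. With the fluidics station as a block Agtr1a was at -0.68 (adjusted p = 0.0836), its sign turned with array weights, the Xist level as a term or non-transgenic array 1 left out, and its adjusted p ran from 0.0836 to 0.985 over the alternatives. The related receptor genes Agtr1b and Agtr2 lay below the brightness filter, at 2.38 against 2.37 and at 2.86 against 2.83.

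The sexes were not equally represented. Xist, the RNA that coats the inactive X chromosome, was above log2 6 on 2 of the 3 labelled transgenic arrays and on 1 of the 3 others. The Y-linked gene Eif2s3y was high on the remaining arrays. Xist averaged 7.18 ± 3.98 against 5.06 ± 4.02 and Eif2s3y 5.13 ± 3.57 against 7.33 ± 3.25. Neither of these sex-linked transcripts passed the test, with adjusted p = 0.738 and adjusted p = 0.675, with the fluidics station as a block their changes were 4.69 and -4.04 in place of 2.12 and -2.20, with single arrays left out they ran from 0.83 to 4.43 and from -4.25 to -0.95, and the other Xist probe sets gave changes from -0.19 to 1.88. The list of sex-linked transcripts had 4 measured members and was too short for the list test, and its median change was -0.90.

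In the labelled transgenic hearts Myh7, the slow beta myosin heavy chain of the fetal mouse ventricle, rose 25.1-fold, from 9.09 ± 0.62 to 13.73 ± 0.10 (log2, SD, n = 3, adjusted p = 0.023). Nppa, which encodes atrial natriuretic peptide, rose 4.58-fold (adjusted p = 0.0257). Ccn2, a matricellular growth factor of fibrotic tissue, rose 3.02-fold (adjusted p = 0.0167). Aqp4, a water channel, fell from 5.53 ± 0.25 to 2.65 ± 0.20 (adjusted p = 0.0167), and since the lower mean lies under the brightness filter at log2 3.285, the fall is given as at least 4.75-fold, measured to that level. Myh6, the alpha myosin heavy chain of the adult mouse heart, was at 16.01 ± 0.02 against 16 ± 0.08, a change of 0.01 ± 0.07 with adjusted p = 0.952, and with median centring its sign turned, to -0.022. This probe set was the brightest of all on 5 of the 6 arrays, at the top of the scale, where a rise may not be measurable, so no lack of change is read from it. In each gene written here as having risen or fallen over all genes, the 3 values of 1 group all lay above the 3 of the other, which chance gives in 10% of genes. The largest changes were named on that condition, and genes chosen for a small p seldom overlap, so this adds no support.

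Other genes that rose included Shisa4 by 5.41-fold, Itgbl1 by 3.88-fold, and Bcl2, an inhibitor of apoptosis, by 3.08-fold. Col8a1, a short-chain collagen, rose 3.02-fold, and Gnao1, a G protein alpha subunit, rose 2.94-fold. Tlr4, the receptor for bacterial lipopolysaccharide, rose 2.56-fold and Rrp12, a ribosome biogenesis factor, 2.4-fold. Prkcd, a protein kinase C isoform, rose 1.77-fold, although its other probe set was at 0.02 and the mean of both, at 0.42, did not pass (adjusted p = 0.0566, in a range from 0.0235 to 0.169 over the alternatives). Cp, the ferroxidase ceruloplasmin, rose 1.74-fold with 4 passing probe sets and was singled out after its values were seen. Tmem50b and Wnk2, a kinase of the family that regulates ion transport, both fell 1.79-fold. Other probe sets of these genes did not always pass, such as that of Aqp4 at -1.28, that of Wnk2 at -0.40, those of Bcl2 between 0.83 and 1.24, 1 of the 2 other Col8a1 probe sets and 2 of the 3 other Tlr4 ones. As the mean of a gene's probe sets, 4 more of them did not pass, Bcl2 at 1.23 (adjusted p = 0.0735), Tlr4 at 0.92 (adjusted p = 0.0613), Wnk2 at -0.62 (adjusted p = 0.0576) and Col8a1 at 1.57 (adjusted p = 0.0502). Over all alternatives their adjusted p ran from 0.028 to 0.188, from 0.0385 to 0.183, from 0.00886 to 0.169 and from 0.00658 to 0.169, in that order. Kcnd2, a subunit of the transient outward potassium channel, changed by -0.83 ± 0.10 and Scara5, a ferritin receptor, by -1.23 ± 0.15. Neither passed, at adjusted p = 0.0588 and adjusted p = 0.0613.

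In all, limma's moderated test called 49 of 22518 probe sets at an adjusted p under 0.05, 40 higher and 9 lower in the labelled transgenic group. Of these, 24 higher and 4 lower ones changed by at least 1 on the log2 scale. With 1 probe set per gene, 25 of 11016 genes passed, 22 higher and 3 lower. At an unadjusted p under 0.05 there were 3689 probe sets, against 1126 expected by chance, 2118 of them higher and 1571 lower. The 2 groups did not overlap at 5172 probe sets, or 23% of those tested, where chance gives 10%. The count of 49 depended on each array, since it was 75 without labelled transgenic array 1 and 5 without non-transgenic array 1, and 0 without any of the other 4 in limma. At an unadjusted p under 0.05 those 4 fits gave 2976 (without labelled transgenic array 2), 2532 (array 3), 3430 (non-transgenic array 2) and 3033 (array 3) probe sets. The count was 2 with the fluidics station as a block, 0 within station 2 (3771 unadjusted) and 0 with the Xist level as a term (3076 unadjusted), the latter pair added after seeing the data. All 49 probe sets kept their sign in each of these fits, and an unadjusted p under 0.05 in those with at least 2 arrays per group. They were chosen on these same arrays, so this adds little support.

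**Figure D1:**
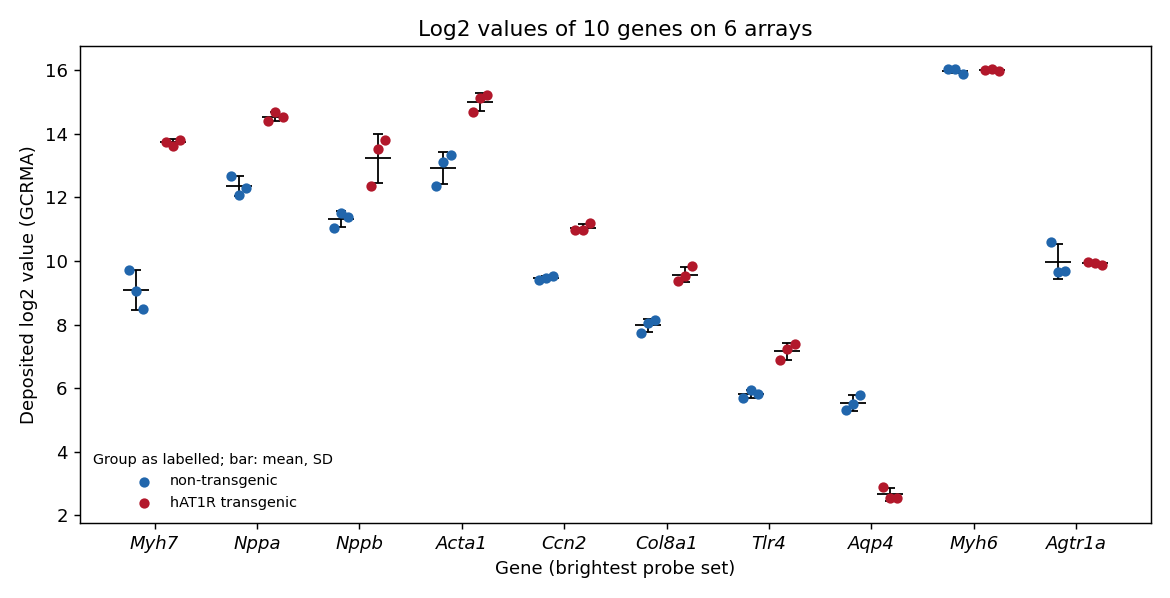
Deposited log2 values (y axis) of 10 genes (x axis) on each of the 6 arrays, with 1 point per array and bars for the mean and SD of each group of 3, blue for non-transgenic and red for labelled transgenic. Myh7 rose from a mean of 9.09 to 13.73 and Aqp4 fell from 5.53 to 2.65. Myh6, at 16 and 16.01, was the brightest probe set on 5 of the 6 arrays, where a rise may not be measurable.

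Station and group overlapped in part. The 3 labelled transgenic arrays and non-transgenic array 1 were washed on station 2, and the other 2 non-transgenic arrays on station 3. With the station as a block, Myh7 changed by 4.01, Nppa by 1.85, Ccn2 by 1.65 and Aqp4 by -2.65, at adjusted p = 0.067 for Myh7 and adjusted p = 0.0706 for the other 3. Over all alternatives the adjusted p ran from 0.00194 to 0.166 for Myh7, from 0.00457 to 0.169 for Nppa, from 0.00194 to 0.169 for Ccn2 and from 0.011 to 0.169 for Aqp4. The values within station 2 were equal to these and add no further evidence, since station 3 held 1 group only and station 2 a single non-transgenic array, assumed in that fit to vary like the others. All 3 labelled transgenic arrays were scanned before the first non-transgenic one, so scan order and group could not be told apart. With the station as a block, and equally within station 2, the list medians given below were 0.57 for hypertrophy, 0.66 for matrix, 0.88 for fibroblast, 0.42 for macrophage and 0.39 for cytokine genes. They were 0.22 for unfolded protein, 0.39 for immediate early, -0.28 for fatty acid, -0.13 for oxidative phosphorylation, -0.19 for citric acid cycle, -0.18 for ion channel and -0.076 for smooth muscle genes.

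The hypertrophy and fetal gene list shifted upward, with a median change of 0.43 (camera, adjusted p = 2.65e-07, and adjusted p = 0.119 with an estimated correlation). Of its 26 measured members, 3 rose over all genes, and none fell. Adjusted over the list alone, 15 rose, 1 fell and 10 did not pass. The 3 were Myh7, Nppa and Ccn2. Adjusted over the list alone the rises included Acta1, the skeletal alpha actin, at 2.07 ± 0.28 (adjusted p = 0.0671 over all genes), and Nppb, which encodes brain natriuretic peptide, at 1.92 ± 0.38 (adjusted p = 0.107). Ankrd1, a stretch-responsive nuclear cofactor singled out after its values were seen, was at 1.34 ± 0.23 (adjusted p = 0.0794). The adult sarcomere and calcium handling list was not called as shifted. It includes very bright probe sets, such as Myh6 at the top of the scale, so no lack of change is read from the list. None of its 30 measured members passed over all genes or adjusted over the list alone in limma, with 6 at an unadjusted p under 0.05. Its median was 0.0029 and its mean -0.01, opposite in sign, and the test pointed down (adjusted p = 0.704). Atp2a2, the calcium pump of the sarcoplasmic reticulum, changed by -0.10 ± 0.06, while 1 of its 5 other probe sets reached -0.90 and the mean of all was -0.35. S100a1 was at 0.36 ± 0.09, or 0.23 as the mean of its 2 probe sets, and Ldb3 at -0.31 ± 0.08 with both of its other probe sets above 0, from 0.16 to 0.19.

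The matrix and fibrosis list shifted upward, with a median of 0.47 (camera, adjusted p = 8.34e-10, and adjusted p = 0.301 with an estimated correlation). Of 52 measured members, 2 rose over all genes, Ccn2 and Col8a1, and none fell. Adjusted over the list alone 14 rose, none fell and 38 did not pass. Among these 14, and singled out after their values were seen, the proteoglycans Bgn and Vcan were at 1.25 ± 0.20 and 1.51 ± 0.28, and the growth factor Tgfb2 was at 1.07 ± 0.15. Another Tgfb2 probe set was at 2.35 and passed over all probe sets. The fibrillar collagen Col1a1 was at 0.83 ± 0.29 (adjusted p = 0.251) and Col3a1 at 0.48 ± 0.30 (adjusted p = 0.493). These collagens were at 1.26 and 0.92 with the station as a block, and Col3a1 was at 0.76 without labelled transgenic array 1, at 0.28 without labelled transgenic array 3 and at 0.26 without non-transgenic array 1, and at 0.73 as the mean of its probe sets. Fibroblast markers, 7 of which are also on the matrix list, had a median of 0.54. None of 13 passed over all genes (8 at an unadjusted p under 0.05), while adjusted over the list alone 8 rose and 5 did not pass. Lum, a collagen-binding proteoglycan, was at 0.86 ± 0.23. The growth factor receptor Pdgfra and the transcription factor Tcf21, singled out after their values were seen, were at 0.68 ± 0.14 and 0.75 ± 0.15, with the other Pdgfra probe sets at 0.15 to 0.76. The fibroblast list passed (adjusted p = 4.37e-05), but not with an estimated correlation (adjusted p = 0.301 with an estimated correlation), nor with fry (adjusted p = 0.0648).

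The macrophage and monocyte list shifted upward, with a median of 0.46 (adjusted p = 1.62e-05, and adjusted p = 0.119 with an estimated correlation). None of 15 measured macrophage and monocyte markers passed over all genes (10 at an unadjusted p under 0.05), while adjusted over the list alone 10 rose and 5 did not pass. Lgals3, a galectin, was at 2.0 ± 0.47, the lysosomal protein Cd68 at 0.96 ± 0.20 and Adgre1, a macrophage surface receptor singled out after its values were seen, at 0.68 ± 0.10. Cd68 was at 0.60 with the station as a block. The cytokine, chemokine and adhesion list shifted upward, with a median of 0.44 (adjusted p = 0.000166, and adjusted p = 0.119 with an estimated correlation). Of its 27 measured genes, Tlr4 alone rose over all genes and 4 rose adjusted over the list alone, with 23 not passing. Among the 4 was Vcam1, a leukocyte adhesion molecule singled out after its values were seen, at 0.86 ± 0.19, or 0.49 with the station as a block. The 2 lists share 4 measured genes. A gauge of RNA integrity, taken from the actin control alone, moved with the groups as well, which does not show that integrity itself differed. The 3' minus 5' log2 difference of the actin control was 0.879 ± 0.074 (SD, n = 3) on the labelled transgenic arrays and 1.01 ± 0.04 on the others, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow.

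The fatty acid oxidation and uptake list shifted downward, with a median of -0.27 (adjusted p = 2.17e-11, and adjusted p = 0.301 with an estimated correlation). Of its 40 measured genes 39 had a negative change. None passed over all genes (21 at an unadjusted p under 0.05), while adjusted over the list alone 8 fell and 32 did not pass. Those 8 included, singled out after their values were seen, the regulators Ppargc1a at -0.71 ± 0.14 and Ppara at -0.55 ± 0.13, the carnitine palmitoyltransferase Cpt2 at -0.42 ± 0.07 and the dehydrogenase Acad11 at -0.49 ± 0.08, with another Cpt2 probe set at -0.15. Plin5, a lipid droplet protein, was at -0.89 ± 0.27 and the thioesterase Acot1 at -0.84 ± 0.31. Plin5 was at -0.43, Acot1 at -0.40 and Ppargc1a at -0.46 with the station as a block. The oxidative phosphorylation list shifted downward, with a median of -0.10 (adjusted p = 8.34e-10, and adjusted p = 0.301 with an estimated correlation). Of 74 oxidative phosphorylation genes 69 had a negative change and none passed, over all genes or adjusted over the list alone, with 16 at an unadjusted p under 0.05. The cytochrome oxidase subunits Cox7c and Cox7a1 were at -0.82 ± 0.22 and -0.25 ± 0.06, with Cox7c at -0.50 when the station was a block. The Cox7c probe set was dim, at 4.07 against 4.89, and the gene's other probe set lay below the brightness filter, so the size of its change is uncertain. The citric acid cycle list shifted downward, with a median of -0.20 (adjusted p = 4.86e-07, and adjusted p = 0.182 with an estimated correlation). Of 21 genes of the citric acid cycle and pyruvate dehydrogenase none passed over all genes (13 at an unadjusted p under 0.05), while adjusted over the list alone 7 fell and 14 did not pass. Pdhx, a component of pyruvate dehydrogenase, was at -0.42 ± 0.07 and Dlst, of the oxoglutarate dehydrogenase, at -0.40 ± 0.07, although its 3 other probe sets lay between -0.24 and -0.08 and the mean of its probe sets was at -0.22 (adjusted p = 0.199, in a range from 0.039 to 0.253 over the alternatives). The list of glycolysis genes was not called as shifted (24 measured, median -0.08, adjusted p = 0.232). With fry's mixed test, which counts changes in either direction, its adjusted p was 9.54e-05. None passed over all genes (8 at an unadjusted p under 0.05), and adjusted over the list alone 2 rose and 1 fell. With no filter on dim probe sets the glycolysis list passed downward, with adjusted p = 0.0486 in a range from 0.0486 to 0.696 over the alternatives. Pfkp, a phosphofructokinase, was at 0.53 ± 0.12 and the hexokinase Hk1 at 0.42 ± 0.14, which was 0.22 with the station as a block and 0.27 without non-transgenic array 3. In the same arrays the cardiomyocyte marker score differed by -0.0673 ± 0.0116, labelled transgenic minus other (SE, n = 3 per group, exact permutation p = 0.1). That score includes Myh6, at the top of the scale, so its size is uncertain. The actin 3' minus 5' difference changed by -0.13 in the same comparison.

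The ion channel and gap junction list shifted downward, with a median of -0.12 (adjusted p = 0.00179, and adjusted p = 0.301 with an estimated correlation), and did not pass with fry (adjusted p = 0.0967). None of 27 passed over all genes (6 at an unadjusted p under 0.05), while adjusted over the list alone 4 fell and 23 did not pass. The 4 included Kcnd2 and Cacna1h, a T-type calcium channel at -1.02 ± 0.16. The angiotensin system and receptor signalling list was not called as shifted. Of its 32 measured members Prkcd rose over all genes, and adjusted over the list alone 3 rose, 1 fell and 28 did not pass. Singled out after their values were seen, the receptor kinase Grk5 was at 1.04 ± 0.12, the growth factor Hbegf at 0.91 ± 0.12, and Rgs2, which shortens signalling from Gq-coupled receptors, at -1.77 ± 0.38, with its other probe sets between -1.65 and -0.13. The list's median was -0.016 and its mean 0.07, opposite in sign, and the test pointed up (adjusted p = 0.349). It passed with fry, at adjusted p = 0.0181, in a range from 0.0181 to 0.603 over the alternatives.

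The unfolded protein and heat shock list shifted upward, with a median of 0.23 (adjusted p = 0.000317, and adjusted p = 0.182 with an estimated correlation). Of 34 unfolded protein and heat shock genes none passed over all genes (15 at an unadjusted p under 0.05), while adjusted over the list alone 5 rose and 29 did not pass. Creld2, a secreted endoplasmic reticulum stress protein singled out after its values were seen, was at 0.70 ± 0.11. The inducible chaperones Hspa1a and Hspa1b were at 2.73 ± 0.82 and 1.88 ± 1.06, with an SD of 1.69 and 2.25 within the labelled transgenic group. Without labelled transgenic array 2, at 8.37 and 11.1, they were at 1.76 and 0.58. The immediate early list shifted upward, with a median of 0.20 (adjusted p = 0.0123, and adjusted p = 0.301 with an estimated correlation). Of 25 immediate early genes none passed over all genes (6 at an unadjusted p under 0.05), while adjusted over the list alone 4 rose and 21 did not pass. The transcription factor Egr1 was at 1.53 ± 0.37, and at 0.70 with the station as a block. Egr3, another such factor, was at 0.96 ± 0.43 with a non-transgenic mean of 2.98, under the brightness filter, and labelled transgenic array 1 lay under it too, so the size of the difference is uncertain. It passed without labelled transgenic array 1 (1.48, adjusted p = 0.0468, in a range from 0.0468 to 0.668) and was at 0.61 without array 3. Ccn1, a matricellular protein singled out after its values were seen, was at 0.90 ± 0.11. The list's call ended without labelled transgenic array 2 (adjusted p = 0.0536) or non-transgenic array 1 (adjusted p = 0.159), with the filter at the upper quartile (adjusted p = 0.0757) and with fry (adjusted p = 0.0516), in a range from 0.000263 to 0.301 over the alternatives.

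Other process lists were not called as shifted, and their members are given as values. Of 36 genes of oxidative stress defence none passed over all genes (10 at an unadjusted p under 0.05) and 2 rose adjusted over the list alone, the quinone reductase Nqo1 at 0.76 ± 0.13 and the plasma glutathione peroxidase Gpx3 at 0.69 ± 0.12. The list's median was 0.03 (adjusted p = 0.84). Of 27 cell death genes Bcl2 alone passed, over all genes and adjusted over the list alone (median 0.05, adjusted p = 0.577). None of 21 cell cycle genes passed over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, median -0.04, adjusted p = 0.349), with the cyclin Ccnd2 at 0.50 ± 0.18 and the cyclin-dependent kinase inhibitor Cdkn1c at -0.49 ± 0.18, or -0.30 without labelled transgenic array 1. None of 24 interferon response genes passed over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, median -0.20, adjusted p = 0.26), with Rsad2 at -0.63 ± 0.26 and Ifit2 at 0.59 ± 0.41. With the station as a block the interferon median was -0.80, and the list then passed (adjusted p = 0.000738). It also passed without labelled transgenic array 3, at a median of -0.43 (adjusted p = 0.00269), and the adjusted p ran from 0.000738 to 0.903 over the alternatives. Its median turned to 0.12 without labelled transgenic array 1 or non-transgenic array 1, and Ifit2 turned to -0.21 with the station as a block. Rsad2 was at -0.34 without labelled transgenic array 1, and Ifit2 ran from 0.34 to 0.996 with single arrays left out, the highest without non-transgenic array 1. None of 17 circadian clock genes passed over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, adjusted p = 0.972), with the repressors Nr1d1 at 0.78 ± 0.63 and Bhlhe40 at 0.61 ± 0.26. The median of the clock list was -0.06 and its mean 0.06, opposite in sign, and with the station as a block Nr1d1 turned to -0.65 and Bhlhe40 was at 0.09, while Ccnd2 of the cell cycle list was at 0.27. Nr1d1 ran from 0.39 to 1.497 with single arrays left out, without non-transgenic arrays 2 and 1.

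Of the other cell types, cardiomyocyte markers had a median of -0.04 (13 measured, adjusted p = 0.103), with the ryanodine receptor Ryr2 at -0.29 ± 0.12 and creatine kinase Ckm at -0.17 ± 0.08. None of them passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 in limma, and the list passed in 4 of 21 alternatives, in a range of adjusted p from 0.00312 to 0.355. Myh6, at the top of the scale, is among these markers, so no lack of change is read from the list. Endothelial markers had a median of -0.0047 (12 measured, none passing over all genes or adjusted over the list alone, 1 at an unadjusted p under 0.05, adjusted p = 0.604), with the fatty acid binding protein Fabp4 at -0.25 ± 0.08 and the growth factor receptor Kdr at 0.24 ± 0.20. Smooth muscle and pericyte markers shifted downward as a list, with a median of -0.16 and none of 12 passing over all genes or adjusted over the list alone, 3 being at an unadjusted p under 0.05 (adjusted p = 0.0123, and adjusted p = 0.43 with an estimated correlation). This call ended with the station as a block (adjusted p = 0.575), with fry (adjusted p = 0.189) and without labelled transgenic array 1 (adjusted p = 0.0937) or non-transgenic array 2 (adjusted p = 0.139), in a range from 0.00105 to 0.759 over the alternatives. The potassium channel regulator Abcc9 was at -0.36 ± 0.08 and the smooth muscle actin Acta2 at -0.33 ± 0.23. None of 6 lymphocyte or 5 erythroid markers passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. Lymphocyte markers had a median of 0.0090 (6 measured, adjusted p = 0.996), with Ptprc at 0.31 ± 0.29 and Cd4 at -0.07 ± 0.12. Erythroid markers had a median of -0.30 (5 measured, adjusted p = 0.215), with Car2 at -0.50 ± 0.34 and the transferrin receptor Tfrc at -0.45 ± 0.66. With the station as a block Fabp4 was at -0.11, Kdr at -0.11, Acta2 at 0.14, Ptprc at 0.74, Cd4 at 0.12 and Tfrc at -0.97. With single arrays left out Car2 ran from -0.86 (without labelled transgenic array 2) to -0.14 (array 3), at -0.32 with the Xist level as a term, and Tfrc from -1.09 (non-transgenic array 3) to -0.07 (array 2). Kdr ran from 0.09 (non-transgenic array 2) to 0.41 (array 1), Acta2 from -0.57 (non-transgenic array 1) to -0.11 (array 2), Ptprc from 0.04 (labelled transgenic array 3) to 0.48 (non-transgenic array 3) and Cd4 from -0.17 to 0.01 (non-transgenic arrays 1 and 3). The means of the probe sets of Ckm and Fabp4 were -0.31 and -0.41.

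Among atrial markers Nppa alone passed, over all genes and adjusted over the list alone. The atrial list was not called as shifted (6 measured, median 0.04, adjusted p = 0.401, and adjusted p = 0.0173 with fry in a range from 0.0173 to 0.735). Skeletal muscle markers had a median of -0.04 and a mean of 0.29, opposite in sign, and the test pointed up (6 measured, adjusted p = 0.972). None of them passed over all genes, Acta1 rose adjusted over the list alone, and the fast troponin Tnni2 was at -0.19 ± 0.17. Schwann cell and neuron markers had a median of 0.115 (6 measured, adjusted p = 0.144, and adjusted p = 0.0327 with fry in a range from 0.0327 to 0.533). None passed over all genes (2 at an unadjusted p under 0.05), and 2 rose adjusted over the list alone, the ubiquitin hydrolase Uchl1 at 0.78 ± 0.17 and the myelin protein Pmp22 at 0.37 ± 0.10. The neutrophil, adipocyte, epicardial and lung lists had 2, 3, 3 and 1 measured members and were not tested. S100a8 and S100a9 of neutrophils were at 0.51 ± 0.60 and 0.23 ± 0.80, and Cidea of adipocytes was at 0.32 ± 0.11. Aldh1a2 and Wt1 of the epicardium were at 0.69 ± 0.45 and 0.17 ± 0.12, and Ager of lung epithelium was at 0.21 ± 0.18. Adjusted over the list alone, Cidea rose and Fabp4 fell among the adipocyte markers, and no neutrophil, epicardial or lung marker passed. With the station as a block Tnni2 was at -0.57, S100a8 at -0.38, S100a9 at -1.12, Aldh1a2 at 0.25 and Wt1 at 0.10. Without labelled transgenic array 1 S100a8 turned to -0.07 and S100a9 to -0.44, Aldh1a2 was at 0.19, Wt1 at 0.30, Ager at 0.32 and Cidea at 0.22, and without array 3 Ager was at -0.0030. Tnni2 turned to 0.0070 without non-transgenic array 1, where S100a8 was at 0.96 and S100a9 at 0.91.

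**Figure D2:**
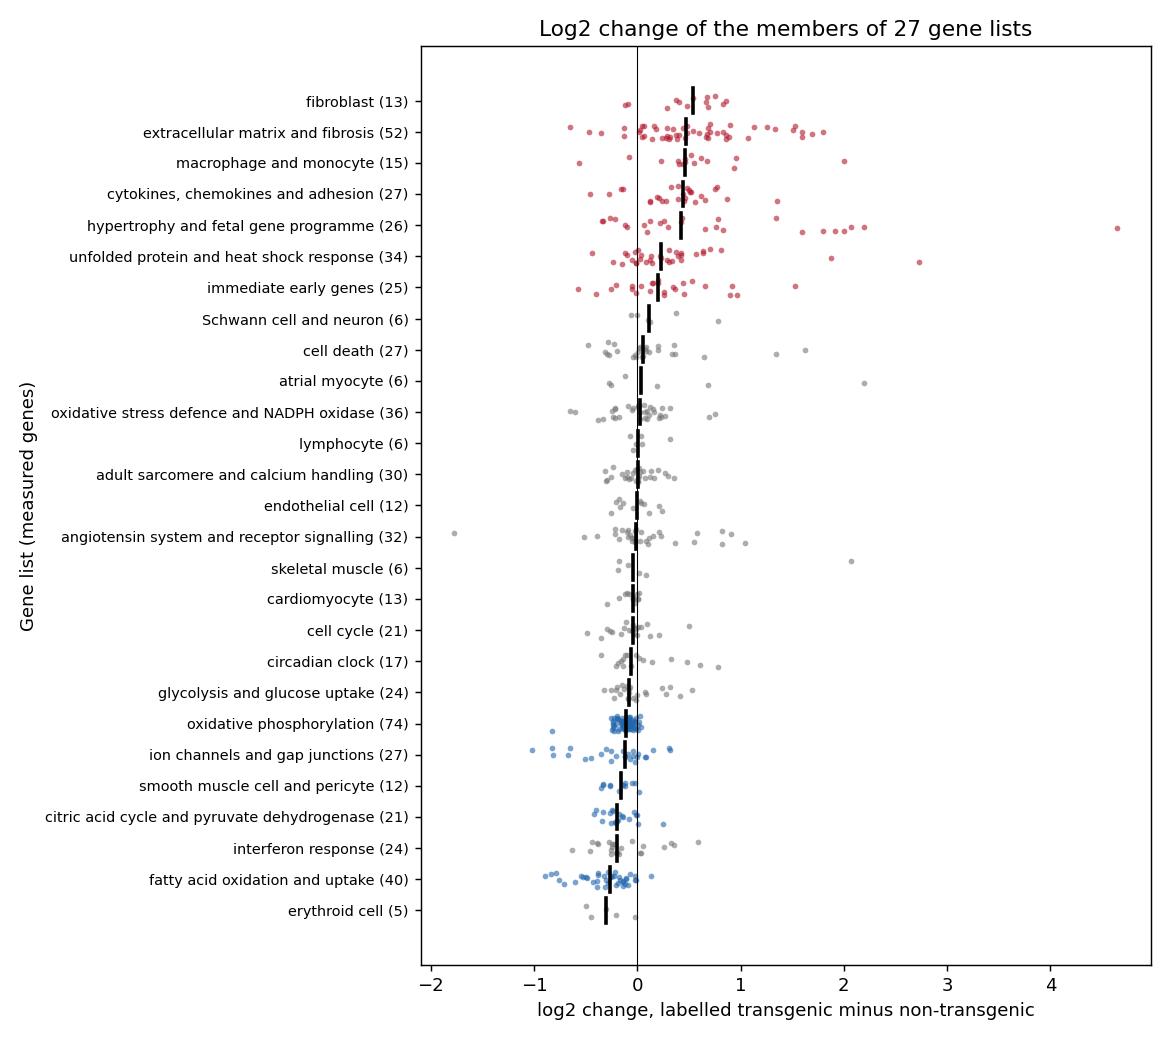
Log2 change (x axis, labelled transgenic minus non-transgenic, 3 arrays each) of every measured member of the 27 gene lists tested (y axis, with the number of measured members), with 1 point per gene and a black bar at each list's median, red for lists that passed upward, blue for lists that passed downward and grey for the others. The fibroblast list had the highest median, 0.54, and among the lists that passed the fatty acid list had the lowest, -0.27.

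In all, 12 of the 27 tested lists passed camera with its preset correlation, 7 upward and 5 downward. None passed with a correlation estimated from the data, where limma's camera gave 5 lists at an unadjusted p under 0.05 and an adjusted p of 0.119 or more, and 12 passed with fry, 8 of them among the first 12. Fry's mixed test, which counts changes in either direction, passed 20 of the 27 lists. A list not called as shifted may thus still hold changed genes.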

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

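The tests of the control probe sets, Xist level, scan order, cell type scores, fibroblast markers, actin difference and typed names were chosen after the results were seen.

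Apart from the actin 3' minus 5' difference, mouse control probe sets entered no comparison of the report. In 4 of 19 of them every labelled transgenic array lay above every other array, where chance gives 5% for each, or about 0.95 in all. Among all probe sets tested the groups did not overlap, in either direction, at 23%. The B1 repeat probe set was higher by 0.59 on the log2 scale (13.74 ± 0.21 against 13.15 ± 0.09, SD, n = 3), and the B2 repeat by 0.08. Another B2 probe set was at 7.92 in both groups. The beta-actin controls were higher by 0.26 at the 3' end and by 0.39 at the 5' end, both of the same transcript. The middle actin probe set, higher by 0.22, overlapped. Each of the 4 that did not overlap had a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The Gapdh controls were at 14.96 against 14.99 at the 3' end and at 14.85 against 14.86 at the 5' end.

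The 49 probe sets that passed could reflect the unequal numbers of Xist-high arrays, the fluidics station or the scan order in place of the transgene. With the Xist level as a term the median ratio of their log2 changes to those without it was 0.988 and the lowest 0.932. The 49 were picked for a small spread within groups that each hold Xist-high and Xist-low arrays. That choice keeps the ratio near 1, so it does not test the sex imbalance. None passed with this term (limma, smallest adjusted p = 0.0718, 3076 at an unadjusted p under 0.05, with 1 residual degree of freedom fewer). With the station as a block the median ratio was 1.03 and the lowest 0.811, and all 49 kept their sign and an unadjusted p under 0.05, but 0 of them passed (limma, 3696 of all probe sets unadjusted), since the groups are then compared within station 2 against non-transgenic array 1 alone, and a single array excludes nothing. Another set, the 51 probe sets at p under 0.001 with a log2 change of at least 1 in a fit without that array, placed it at a median of 0.116 (interquartile range -0.108 to 0.37) between the other non-transgenic arrays at 0 and the labelled transgenic mean at 1, with 40 (78.4%) under 0.5, short of the 95% set beforehand, so station and group cannot be told apart for these 51 nor for the 49. Scan order and group cannot be told apart either, since 0 non-transgenic arrays were scanned before the last labelled transgenic one, and the transgene stays open as an untested cause.

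The fibroblast and macrophage lists passed upward in camera, but not with an estimated correlation (adjusted p = 0.301 and adjusted p = 0.119), and none of their markers passed over all genes. A lower share of cardiomyocyte RNA would raise the markers of other cell types alike. Yet the fibroblast minus vascular score was higher in the labelled transgenic than in the other group by 0.589 ± 0.113 (SE, 2-sided exact permutation p = 0.1, the smallest possible) and the macrophage minus vascular score by 0.636 ± 0.1. The vascular score itself changed by -0.101 ± 0.0988 (exact permutation p = 0.4), so these marker lists did not rise alike. The fibroblast and macrophage lists were compared because they had passed upward, and the vascular score holds the smooth muscle list, which had passed downward. That choice largely set the differences, so they do not decide whether a lower share contributed. The cardiomyocyte score differed too, by -0.0673 ± 0.0116 (labelled transgenic minus other, exact permutation p = 0.1). It includes Myh6, at the top of the scale, so its size is uncertain. More fibroblasts, each as before, would raise their markers alike. Of 10 bright markers 2, Dpt at -0.087 ± 0.091 and Dcn at 0.38 ± 0.06, lay below the list's median by more than 2 standard errors. They were picked from the 10 without correction and the median's own error was left out, so this does not decide the question. More RNA degradation in these arrays would widen the actin 3' minus 5' difference, which instead changed by -0.13. A lower share of cardiomyocyte RNA, more fibroblasts, with or without altered expression, more macrophages, and less degradation stay open as candidate explanations.

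The typed names carried the other group's word on 6 of 6 arrays, so either group labels exchanged between the 2 groups or wrong typed words could be the reason. No probe set used here is annotated to the human transgene, which keeps this open, and the 2 cannot be told apart.

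The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 49 probe sets and the highest of the others 9, in the one that follows the Xist level, so 1 of 10, the real one itself, gave 49 or more. For gene lists the real division gave 12 and the highest of the others 11, with labelled transgenic array 1 beside non-transgenic arrays 1 and 2. The real one was the 1 of 10 that gave 12 or more, but the others ran from 2 to 11. Camera at the preset correlation thus called lists in divisions that mix the groups too, and 12 hardly stands out.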

How the results depend on the processing

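The fits within station 2 and with the Xist level as a term, and their values here, were chosen after seeing the data, and all other alternatives were set beforehand. All 49 probe sets that passed kept their sign and an unadjusted p under 0.05 in every alternative in which they were tested (30 of them with the filter at the 75th percentile), apart from the mean of a gene's probe sets, which has no single probe sets. The 49 were chosen on these same arrays, so this adds little support. Named genes gave 1646 alternative values, of which 1414 kept direction and side of the threshold, 159 lost the call, 43 gained one and 30 changed sign, in 13 genes. Gene lists gave 562, of which 494 kept both, 23 lost the call, 11 gained one and 34 changed sign, in 10 lists. No gene or list that had passed changed sign, and none passed in an alternative in which its sign changed. The interferon, angiotensin and atrial lists changed sign in some alternatives and passed in others, the angiotensin and atrial lists with fry alone. The cause of these changes was not tested, except that fewer probe sets or arrays enter a filtered or reduced fit. Brightness limits what could be tested, since probe sets under log2 3.285 were left out.

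The counts of probe sets and genes that passed were 15 and 10 with no filter on dim probe sets, 416 and 241 with the filter at the 75th percentile, and 108 and 68 with an intensity trend. They were 2 and 2 with the fluidics station as a block, 0 and 0 within station 2 (limma, 3771 probe sets unadjusted) and 0 and 0 with the Xist level as a term (3076 unadjusted). The mean of a gene's probe sets gave 50 genes. With arrays left out in turn they ran from 0 to 75 probe sets and from 0 to 42 genes. By array left out the probe sets numbered 75 and 0 and 0 for labelled transgenic arrays 1, 2 and 3, and 5, 0 and 0 for the non-transgenic ones, with 2532 to 3455 unadjusted in the last 5. Gene lists that passed numbered 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 11 to 14 in the other alternatives.

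With the replicate number as a block 0 probe sets and 0 genes passed (limma, 3324 probe sets unadjusted). Deviations from the group means of arrays that share a number correlated at -0.083, -0.174 and -0.007, and no array correlated best with its own number. Arrays that share a number differed in Xist level each time, at 9.48 against 2.49, 2.58 against 9.69 and 9.48 against 3.01. A difference in sex could hide a pairing, so this check does not decide whether the numbers pair the arrays.

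Changes of sign were as follows. With no filter the median of the angiotensin list was 0.0149 and of the skeletal muscle list 0.0115. With the filter on at least 3 arrays the atrial list was at -0.117. With quantile normalization the lymphocyte list was at -0.00402. With median centring Myh6 was at -0.022, the sarcomere list at -0.0316, the oxidative stress list at -0.00489 and the lymphocyte list at -0.0255. With array weights Agtr1a was at 0.07 and the angiotensin list at 0.026. With the mean of a gene's probe sets Ldb3 was at 0.012, the angiotensin list at 0.0577 and the circadian list at 0.00355. With the fluidics station as a block, and with equal values within station 2, Myh6 was at -0.026, Ifit2 at -0.214, Nr1d1 at -0.65, Kdr at -0.106, Acta2 at 0.14, Cd4 at 0.121, S100a8 at -0.383 and S100a9 at -1.125. The sarcomere list was then at -0.0389, the angiotensin list at 0.0406 and the endothelial list at 0.12. With the Xist level as a term Agtr1a was at 0.034, Xist at -0.189, the angiotensin list at 0.00899 and the lymphocyte list at -0.0115.

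With arrays left out in turn, S100a8 ran from -0.067 to 0.957, S100a9 from -0.438 to 0.913, Ager from -0.003 to 0.324, Agtr1a from -0.219 to 0.263, Tnni2 from -0.288 to 0.007, Myh6 from -0.035 to 0.04 and Cd4 from -0.171 to 0.013. List medians ran from -0.0242 to 0.0283 for the sarcomere, -0.425 to 0.122 for the interferon, -0.0221 to 0.0576 for the angiotensin, -0.086 to 0.0186 for the endothelial and -0.0788 to 0.139 for the atrial list. They ran from -0.0118 to 0.104 for cell death, -0.0637 to 0.0624 for the circadian clock and -0.0302 to 0.0551 for lymphocytes.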

Other observations

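The genes named in this part were chosen after their values were seen, and the test of neighbouring genes was set beforehand. P4ha1, a subunit of the collagen prolyl hydroxylase, was higher in the labelled transgenic group by 1.24 ± 0.12 (log2, SE, n = 3 per group, adjusted p = 0.0351 in limma). Apoe, a lipoprotein component, was higher by 0.71 ± 0.08 (adjusted p = 0.0478) and Sorl1, a sorting receptor for lipoproteins among other cargo, by 1.06 ± 0.07 (adjusted p = 0.023). Synpo, an actin-associated protein, was higher by 1.24 ± 0.13 (adjusted p = 0.041). Of the 49 probe sets that passed, 6 carried no single gene name and the rest covered 38 genes.

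Genes at an adjusted p under 0.10 were tested for lying side by side, or with 1 tested gene between, more often than chance. The 240 genes held 13 such pairs, against a mean of 10.4 and a central 95% range from 5 to 17 in 10000 random draws of as many genes (1-sided permutation p = 0.247). The bound written beforehand for no clustering was met, but that range is too wide to exclude a small excess, so clustering and chance cannot be told apart here.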
